A study of Mus musculus with 48 samples.

How the data were processed

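The values are the deposited RPKM values for 21558 genes in 48 columns, and each column holds a pool of tissue from 3 mice. Per the submitters' processing notes the reads were handled with CASAVA 1.8 and HISAT; the HISAT version, the genome build and the annotation are not given in the sources used here. Raw reads were not analysed here. The 8 series of 6 libraries were taken from the sample labels, never from the values, and 0 columns were left out. A pair of early free-moving series carry the same labels, as do a pair of early unloaded series, so they are called a and b. The number in each library title (1, 5, 9, 13, 17 or 21) has no unit in the labels. It was taken as a time of day in hours, with a period of 24, and this is an assumption. The labels do not say whether the same mice stand behind 1 number in different series, and correlations between libraries of 1 number gave no sign of pairing (median r 0.080 against −0.017 for other pairs, 168 pairs of 1 number). The number was therefore a block in the model and not a subject.

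Checks of the table came first. No pair of libraries was identical, and the highest correlation between libraries of 1 series was 0.995; correlations across series were not checked for this. Read depth is not stated in the sources used here and was recovered from the smallest steps between RPKM values, with gene lengths from GENCODE M21 for 21191 genes. It came to 28.3 M to 55.3 M reads per library (median 38.1), where 61.6% to 68.5% of the low values (up to 12 reads) were whole numbers of reads within 0.02 reads, against 4.0% by chance. This is an estimate from the values. Positions are those of GRCm38 with GENCODE M21, and matched by symbol; Ddit3, Zc3h11a and Aldoa each have a pair of gene IDs there, and Fam174c and Gpr52 have no match.

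Differences were fitted with limma on log2(RPKM + 0.5) for the 13685 genes with mean RPKM of at least 0.5, all 48 libraries in 1 fit with a term for each series and each title number (35 residual degrees of freedom) and an intensity trend in the variance. A gene was called at an adjusted p below 0.05 (Benjamini-Hochberg over all tested genes, two-sided). The log2 values printed are from this fit, so their folds differ a little from ratios of mean RPKM. There were 12 comparisons. Early unloading is the mean of both unloaded early series less the mean of both free-moving early series. Noise and low pressure were applied together and cannot be parted, and the early and late series differ in period and age together. Rhythm was a sine and cosine of the title number with 24 as period, fitted over all series and compared between them.

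The choice of comparisons, gene lists, thresholds and a first set of alternatives was made before the data were examined. Those alternatives were a pseudocount of 0.1, no expression filter, quantile normalization, array weights, only the series compared, no term for the title number, each title number left out in turn, each of the 4 early pairs of series, and camera with an estimated correlation or fry for lists. Chosen after the data had been seen were a covariate for the mitochondrial share of RPKM (log2 odds), removal of a length and GC trend, a table without mitochondrial genes rescaled to its former sum, and fits without early unloaded series a number 9 or early free-moving series a number 1. Quantile normalization and the covariate for lists, and the covariate for the correlations between series of 1 label, were also chosen then. The former sums are larger at a larger mitochondrial share (337798 RPKM at 12.11%, 628251 RPKM at 62.42%). The rescaled table therefore raises all other genes with the share, and a turn of direction on it is partly built in.

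The named genes follow a rule set before the data were examined. For each comparison they are the 8 largest rises and the 8 largest falls among called genes with a series mean of at least 1 RPKM and 1 sign in at least 5 of 6 title numbers, and up to 4 members of each list past its threshold by smallest p. Where fewer than 5 genes pass, the 5 with the smallest p are given as values that did not pass. Fos, Avp, Oxt, Crh, Pomc, Hcrt, Pmch and Ttr are given in the main comparisons whatever their p. For rhythm they are the 10 largest amplitudes and every detected core clock and output gene. Not every gene the rule returns is printed. Title numbers with 1 sign are counted within each comparison.

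There are 40 lists, written from textbook knowledge. On rhythm and neuroendocrine function they are core clock activators and repressors, clock output bZIP factors, suprachiasmatic nucleus markers, feeding and arousal neuropeptides, neurohypophysial and releasing hormones, opioid and tachykinin precursors, thyroid hormone-responsive genes and glucocorticoid-responsive genes. On stress and signalling they are immediate early genes, heat shock chaperones, cold-inducible RNA-binding proteins, unfolded protein response, hypoxia and HIF targets, NRF2 and oxidative stress, interferon-stimulated genes, NF-kB and cytokine genes. On metabolism they are nuclear-encoded respiratory chain, mitochondrially encoded genes, cholesterol synthesis, glycolysis and cytosolic ribosomal proteins. On transmission they are ionotropic glutamate receptors, GABA-A receptor subunits and pan-neuronal genes. On cells and tissue they are astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, microglia, endothelial, mural, ependymal and tanycyte, choroid plexus, meningeal fibroblast, blood cells, anterior pituitary, thalamus, striatum, cortex and hippocampus, hypothalamic transcription factors and muscle contractile genes.

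Lists were tested with camera from limma at a preset correlation between genes of 0.01, with p adjusted over the 40 lists within a comparison. Camera compares a list with all other genes. The same test with a correlation estimated from the data is given beside it. The fry test asks whether the genes of a set move on balance one way; it does not compare the set with other genes. Members are counted as called over all genes, and again adjusted over the list alone.

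The mitochondrial share was compared between series with two-sided permutation tests, exact where all arrangements could be listed, adjusted over 10 comparisons. For each result the libraries were regrouped in 100 splits, of which the real one is 1, and the calls counted again. The p-values measure only the spread between these pools and not between mice. The fit was tested on simulated data, where 98 and 100 of 100 genes changed by log2 1 and 2, up or down, were recovered with 14 false calls. Of 200 rhythmic genes at amplitude 0.6, 200 were recovered, with 4 false calls and a median peak error of 0.22. The simulated noise was independent between genes. In the real data 1 component held 48.27% of the variance left by series and title number. The simulation therefore does not show how many calls are false in the real data. Array weights gave warnings that the convergence tolerance was not achievable. Work was done in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.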

Results

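RNA sequencing of mouse hypothalamus was available for 48 libraries, each a pool from 3 male mice, as deposited RPKM values for 21558 genes. Mice were either moving freely or kept in hind limb unloading, a ground model of weightlessness. They were sampled in an early period (2 months in the labels) or a late one (3 months). Late series were kept either at 10 dBA and normal pressure, here called quiet, or at 85 dBA and 0.9 atm, here called noise. All early series were quiet. Each of the 8 series holds 6 libraries numbered 1, 5, 9, 13, 17 and 21 in their titles. A pair of early free-moving series share their labels, and so do a pair of early unloaded series. Each late condition is 1 series, so a late difference cannot be told apart from other differences between those series. Adjusted p-values for genes are two-sided and from limma over 13685 genes, ± after a log2 value is its standard error, and ± after an RPKM value is the SD. The p-values measure only the spread between these pools.

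The share of all RPKM in the 13 mitochondrially encoded genes varied widely between libraries and series. It was 41.8 ± 16.3% and 44.5 ± 7.36% in early free-moving series a and b, and 20.5 ± 13.8% and 34.3 ± 8.80% in early unloaded series a and b (n = 6 each). It was 11.5 ± 1.68% in the late quiet free-moving series and 14.0 ± 1.32% in the late quiet unloaded series. With noise it was 28.3 ± 8.55% in free-moving and 33.6 ± 17.3% in unloaded mice (n = 6 each). The first principal component of all genes held 66.41% of the variance and followed the log2 odds of this share (r = 0.9589 over 48 libraries). RPKM values are shares of a total, so a fall of mitochondrial RNA raises every other gene. Calls are therefore given as deposited, after quantile normalization, and with the mitochondrial share as a covariate. The covariate was chosen after the data had been seen. Where the share differs with a condition, the covariate also takes away effects of that condition that run with the share.

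**Figure D1:**
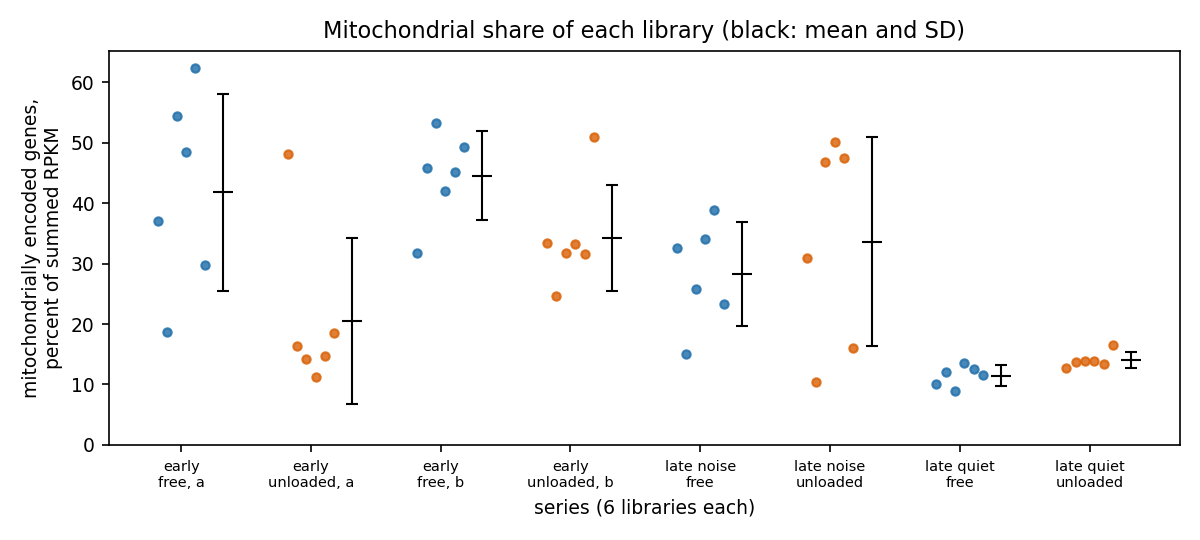
Share of RPKM in mitochondrially encoded genes (%, vertical axis) in each library of the 8 series (horizontal axis), with free-moving series in blue, unloaded series in orange, and black marks for mean and SD. The late quiet series lie lowest and vary least.

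To ask what hind limb unloading does in the early period, both unloaded series were compared with both free-moving series (n = 12 each). Mitochondrial transcripts were lower with unloading, though the calls of this comparison pass with unloaded series a and not with b alone, and end without title number 17. mt-Co2 (ENSMUSG00000064354.1, chromosome M, 7013 to 7696), a subunit of cytochrome c oxidase, fell in the limma fit (log2 −1.08 ± 0.26, adjusted p = 0.0043, lower in 6 of 6 title numbers; 13461 ± 7891 against 27069 ± 12631 RPKM). mt-Atp8 (−1.35) and mt-Nd1 (−1.06) fell as well. Of the 13 mitochondrially encoded genes 12 fell, all 13 when adjusted over the list alone, with a median of −1.17 relative to all genes (camera adjusted p = 5.5e-29, and 0.037 with an estimated correlation). After quantile normalization mt-Co2 moved by −0.10 and 3 of the 13 genes stayed lower, and the sign of mt-Cytb turned from −0.94 to 0.11. Quantile normalization gives each rank 1 value in all libraries, so it takes away differences at the highest ranks by construction. Most mitochondrially encoded genes lie there, so these values do not test their fall. The mitochondrial share itself was 27.4 ± 13.1% against 43.2 ± 12.2% (two-sided permutation p = 0.0069, adjusted 0.017).

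Sgk1, Plin4 and Arl10 were among the largest rises with early unloading. Sgk1 (ENSMUSG00000019970.15, chromosome 10, 21882184 to 21999903), a kinase induced by corticosteroids, rose by log2 1.02 ± 0.27 (limma adjusted p = 0.0051, higher in 5 of 6 title numbers; 15.4 ± 9.27 against 8.14 ± 7.92 RPKM, n = 12 each). Plin4 (ENSMUSG00000002831.13, chromosome 17, 56100591 to 56109803), a lipid droplet coat protein, rose by log2 1.01 ± 0.20 (adjusted p = 0.0043, 6 of 6; 3.17 ± 2.11 against 1.33 ± 1.16 RPKM). Arl10 (ENSMUSG00000025870.10, chromosome 13, 54575015 to 54581128), a small GTPase, rose 2.14-fold (log2 1.09 ± 0.31, adjusted p = 0.0067, 6 of 6; 7.11 ± 5.47 against 3.01 ± 2.79 RPKM). Of 15 glucocorticoid-responsive genes 11 rose and 0 fell, also when adjusted over the list alone, among them Cdkn1a (0.81) and Fkbp5 (0.55). Their median was 0.18 above that of all genes, and camera did not set the list apart (adjusted p = 0.18).

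Crh, Hcrt and Pmch rose and Pomc fell with early unloading. Crh (ENSMUSG00000049796.4, chromosome 3, 19693401 to 19695396), the releasing hormone of the stress axis, rose by log2 0.35 ± 0.12 (limma adjusted p = 0.016, higher in 6 of 6 title numbers; 8.38 ± 2.27 against 6.54 ± 2.27 RPKM, n = 12 each). Hcrt (ENSMUSG00000045471.4, chromosome 11, 100761069 to 100762931), which encodes orexin, rose by 0.38 ± 0.13 (adjusted p = 0.019, 5 of 6). Pmch (ENSMUSG00000035383.7, chromosome 10, 88091072 to 88092375), melanin-concentrating hormone, rose by 0.89 ± 0.28 (adjusted p = 0.011, 5 of 6; 256.8 ± 114 against 137.9 ± 94.0 RPKM). Pomc (ENSMUSG00000020660.6, chromosome 12, 3954951 to 3960642), the melanocortin precursor, fell (−0.63 ± 0.23, adjusted p = 0.025, 5 of 6). Pomc is also a pituitary transcript and reached 362.3 RPKM in unloaded series a number 9, a library rich in pituitary hormones; without that library Pomc fell further (−0.9, adjusted p = 0.0035), while it was 0.09 in unloaded series b against free-moving series a. Avp (log2 0.29 ± 0.17, adjusted p = 0.14), Oxt (−0.13 ± 0.13, adjusted p = 0.38), Fos (−0.37 ± 0.21, adjusted p = 0.12) and the transthyretin gene Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321; 0.77 ± 0.58, adjusted p = 0.25) did not pass. The sign was shared by 5, 4 and 5 title numbers for Avp, Fos and Ttr. After quantile normalization Avp (0.58, adjusted p = 0.035) and Fos (−0.61, adjusted p = 0.038) did pass, and Crh (0.10, adjusted p = 0.52) and Hcrt (0.31, adjusted p = 0.052) did not. With the covariate none of these genes passed, with Crh at 0.19 (adjusted p = 0.96), Hcrt at 0.04 (0.99), Pmch at 0.01 (1) and Pomc at −0.49 (0.95).

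Neuronal and metabolic lists rose with most other genes in early unloading. In the limma fit 11 of 15 ionotropic glutamate receptors (Grik3 0.61, Grin1 0.41), 9 of 14 GABA-A receptor subunits and 7 of 10 pan-neuronal genes (Rbfox3 0.62, Syn1 0.58) rose, and 0 fell in each. Adjusted over the list alone the counts were 13, 9 and 8. Of 13 glycolysis genes 10 rose (Eno2 0.50, Hk1 0.49), as did 8 of 14 hypoxia and HIF targets (Bnip3 0.48, Vegfa 0.48), 11 of 15 core clock genes (Nr1d1 0.54, Cry2 0.48) and 8 of 14 hypothalamic transcription factors, with 0 falling. None of these lists stood apart from other genes by camera, with adjusted p from 0.097 for the glutamate receptors to 0.63 for the hypoxia targets. Astrocyte genes rose in 7 of 11 and fell in 1 (adjusted p = 0.98).

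Some lists lagged behind other genes in early unloading. With the covariate 0 of the 40 lists passed there with an estimated correlation. Of 18 interferon-stimulated genes 0 rose and 2 fell (Oas1a −0.26, Bst2 −0.28), with a median of −0.32 relative to all genes (camera adjusted p = 1.2e-07, and 0.037 with an estimated correlation). Adjusted over the list alone 0 fell, and after quantile normalization 7 did. Of 36 cytosolic ribosomal protein genes 2 rose (Rpl3 0.29) and 8 fell (Rpl26 −0.40, Rps24 −0.35), 1 and 4 adjusted over the list alone, with a relative median of −0.36 (adjusted p = 3.3e-23, and 0.2 with an estimated correlation). Of 10 ependymal and tanycyte genes 2 rose (Foxj1 0.33, Rarres2 0.30) and 2 fell (Dynlrb2 −0.32, Ccdc153 −0.29), with a relative median of −0.43 (adjusted p = 3.5e-06, and 0.037 with an estimated correlation). Blood cell genes fell in 1 of 7 (S100a8 −0.76, relative median −0.69, camera adjusted p = 6.6e-09, and 0.069 with an estimated correlation). Oligodendrocyte and myelin genes rose in 3 and fell in 2 of 13 (relative median −0.24, adjusted p = 6.5e-05, and 0.2 with an estimated correlation). Microglia genes rose in 4 of 12 and fell in 1, Aif1 (−0.45; list adjusted p = 0.094), and 0 of 5 anterior pituitary genes were called.

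In all, early unloading raised 6970 and lowered 257 genes in limma (96.4% higher), with a median shift of all genes of 0.23, and 11 genes changed more than 2-fold. After quantile normalization the split was 1521 and 1263 (54.6% higher), and on a table without mitochondrial genes and rescaled it was 301 and 3183, so the direction of the bulk turns with the scaling. That table keeps each library's former sum, which is larger at a larger mitochondrial share, so part of this turn is built in. With the covariate 1 gene rose and 0 fell, against 719 at an unadjusted p below 0.05, and 0 genes were called in all 3 fits. Unloaded series b alone gave 0 genes against free-moving series a and 3 against b, while 6466 of the called genes had 1 sign in all 4 pairs of series; this is partly built in, as the genes were called on the mean of these pairs and the pairs share series. They also hang on single title numbers, with 0 genes called without number 17 and 21 without number 9.

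To ask whether unloading acts in the late period without noise, the late quiet unloaded series was compared with the late quiet free-moving series (n = 6 each). Gabrb2, Klhl11 and Kcna3 fell the most. Gabrb2 (ENSMUSG00000007653.12, chromosome 11, 42419757 to 42629028), a GABA-A receptor subunit, fell 3.78-fold (log2 −1.92 ± 0.17, limma adjusted p = 1.5e-10, lower in 6 of 6 title numbers; 1.56 ± 0.25 against 7.35 ± 1.31 RPKM). Klhl11 (ENSMUSG00000048732.5, chromosome 11, 100462614 to 100472741), a ubiquitin ligase adaptor, fell (log2 −1.91 ± 0.17, adjusted p = 1.5e-10, 6 of 6; 1.64 ± 0.329 against 7.46 ± 0.52 RPKM). The potassium channel gene Kcna3 (ENSMUSG00000047959.4, chromosome 3, 107036169 to 107038070) fell (−1.90 ± 0.19, adjusted p = 2.4e-09, 6 of 6), and so did the orphan receptor gene Gpr165 (ENSMUSG00000031210.10, chromosome X, 96713441 to 96719388; −1.61 ± 0.29, adjusted p = 0.00028, 6 of 6; 5.38 ± 0.985 against 17.3 ± 2.09 RPKM). Gabrb2, Klhl11 and Gpr165 were low in early free-moving series a as well (0.6053, 0.5819 and 1.344 RPKM). The late quiet free-moving series was thus high for them against that series too. It is also the reference for noise in free-moving mice and for unloading with noise. Both interactions and the free-moving comparison of late against early use it as well. Of 14 GABA-A receptor subunits 0 rose and 3 fell (among them Gabrb1 −0.60), with a relative median of −0.29 (camera adjusted p = 0.0018, and 0.8 with an estimated correlation).

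The largest rises in late quiet unloading included Lrg1 (ENSMUSG00000037095.8, chromosome 17, 56119678 to 56122001), a secreted vascular and acute-phase glycoprotein. It rose 2.58-fold (log2 1.37 ± 0.23, limma adjusted p = 0.00014, higher in 6 of 6 title numbers; 2.89 ± 1.00 against 0.787 ± 0.259 RPKM, n = 6 each). Npas4 (ENSMUSG00000045903.9, chromosome 19, 4984355 to 4990316), an activity-dependent transcription factor, rose 2.5-fold (1.32 ± 0.17, adjusted p = 1.2e-06, 6 of 6; 7.95 ± 2.12 against 2.85 ± 0.847 RPKM). Agrp (ENSMUSG00000005705.10, chromosome 8, 105566698 to 105637393), an appetite-stimulating peptide of the arcuate nucleus, rose 2.49-fold (1.31 ± 0.32, adjusted p = 0.0057, 6 of 6; 10.1 ± 4.14 against 3.74 ± 1.55 RPKM). Npy (ENSMUSG00000029819.6, chromosome 6, 49822710 to 49829507), made by the same neurons, rose by 0.93 (adjusted p = 0.0047). Avp, vasopressin, rose 1.76-fold (0.82 ± 0.24, adjusted p = 0.022, 6 of 6; 1373 ± 310 against 782 ± 193 RPKM) and Crh by 0.54 ± 0.17 (adjusted p = 0.032, 6 of 6). Oxt (0.43 ± 0.18, adjusted p = 0.11), Fos (0.27 ± 0.29, adjusted p = 0.59), Hcrt (0.44 ± 0.19, adjusted p = 0.12), Pomc (−0.24 ± 0.33, adjusted p = 0.67), Pmch (0.20 ± 0.39, adjusted p = 0.78) and Ttr (1.16 ± 0.82, adjusted p = 0.37) did not pass.

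Ribosomal and respiratory genes also rose in late quiet unloading. Of 36 cytosolic ribosomal protein genes 25 rose and 0 fell (Rps16 0.47, Rpl23 0.43), 33 adjusted over the list alone, with a relative median of 0.42 (camera adjusted p = 2.5e-13, and 0.8 with an estimated correlation). Of 30 nuclear-encoded respiratory chain genes 12 rose (Ndufb9 0.54, Cox5b 0.50) and 0 fell (relative median 0.32, adjusted p = 4.9e-05, and 0.8 with an estimated correlation). Of 9 neurohypophysial and releasing hormone genes 3 rose, 6 adjusted over the list alone (relative median 0.41, adjusted p = 0.02, and 0.8 with an estimated correlation). Of 18 interferon-stimulated genes 5 rose (Ifitm3 0.65, Irf7 0.59) and 1 fell (Ifit2 −0.55), and of 10 endothelial genes 3 rose (Ly6c1 0.69, Esam 0.48, Cldn5 0.46), though neither list passed camera (adjusted p = 0.1 and 0.17). Immediate early genes rose in 2 and fell in 1 of 16 (Nr4a3 −0.74; adjusted p = 0.69). Of 17 cholesterol synthesis genes 0 were called, while the list lay −0.27 from all genes (adjusted p = 0.033, and 0.96 with an estimated correlation). Mitochondrial genes made up a share of 14.0 ± 1.32% against 11.5 ± 1.68% (two-sided exact permutation p = 0.0065, adjusted 0.017). In all 1283 genes rose and 462 fell in limma (73.5% higher), 1940 and 1980 after quantile normalization (49.5% higher) and 3084 and 971 with the covariate; 1126 and 458 were called in all 3 fits. As deposited the count was 619 without title number 13, 816 without 17 and 858 without 5, and 7106 with only the compared series.

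To ask whether unloading acts under noise and low pressure, the unloaded noise series was compared with the free-moving noise series (n = 6 each). Only Lrg1 and Agrp were called by limma, against 855 genes at an unadjusted p below 0.05. Lrg1 rose 3.54-fold (log2 1.82 ± 0.23, adjusted p = 1.5e-05, higher in 6 of 6 title numbers; 6.53 ± 3.43 against 1.38 ± 0.555 RPKM). Agrp rose 3.16-fold (1.66 ± 0.32, adjusted p = 0.036, 6 of 6; 50.4 ± 27.1 against 14.7 ± 5.77 RPKM). Both passed in all 3 fits. Lrg1 also passed with each title number left out, while Agrp passed only without number 1 and not without any other (adjusted p from 0.071 to 0.94), nor without the filter (0.11) or the term for the title number (0.13). Of 100 groupings of the libraries 5 called at least as many genes, so chance is not excluded for the count. The next values did not pass: the orphan nuclear receptor gene Nr4a3 (−0.86 ± 0.18, adjusted p = 0.14), Gm3558 (−0.64 ± 0.14, adjusted p = 0.19) and the signal peptidase gene Sec11c (−0.39 ± 0.09, adjusted p = 0.29). Avp (0.64 ± 0.24, adjusted p = 0.75), Fos (−0.50 ± 0.29, adjusted p = 0.77), Pomc (−0.75 ± 0.33, adjusted p = 0.77), Hcrt (−0.58 ± 0.19, adjusted p = 0.73), Oxt (adjusted p = 0.83), Crh (0.8), Pmch (0.77) and Ttr (0.79) did not pass either.

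By camera at the preset correlation 12 of the 40 lists stood apart in late unloading with noise, against 0 with an estimated correlation and 0 by fry, and 0 members of the lists given here were called by limma. Heat shock chaperones lay −0.13 from all genes (13 tested, 4 lower when adjusted over the list alone, camera adjusted p = 1.5e-06, and 0.34 with an estimated correlation). Glucocorticoid-responsive genes lay 0.20 above (15 tested, adjusted p = 5.4e-05, and 0.39 with an estimated correlation), and striatum genes 0.44 above (9 tested, adjusted p = 3.5e-06, and 0.34 with an estimated correlation). The median shift of all genes was −0.11. Their pools had a mitochondrial share of 33.6 ± 17.3% against 28.3 ± 8.55% (two-sided exact permutation p = 0.5).

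To ask what noise with low pressure does in free-moving mice, the late free-moving noise series was compared with the late quiet free-moving series (n = 6 each). Several peptide hormone genes rose. Avp (ENSMUSG00000037727.6, chromosome 2, 130580620 to 130582554) rose 3.64-fold (log2 1.86 ± 0.24, limma adjusted p = 8.3e-08, higher in 6 of 6 title numbers; 2945 ± 1035 against 782 ± 193 RPKM). Oxt (ENSMUSG00000027301.7, chromosome 2, 130576173 to 130577054), oxytocin, rose 2.64-fold (1.40 ± 0.18, adjusted p = 6.7e-08, 6 of 6; 1676 ± 535 against 615 ± 137 RPKM). Agrp rose 3.49-fold (1.8 ± 0.32, adjusted p = 1.2e-05, 6 of 6), Hcrt by 0.87 ± 0.19 (adjusted p = 0.00019, 6 of 6; 378.7 ± 48.5 against 211.2 ± 52.2 RPKM) and Pomc by 1.05 ± 0.33 (adjusted p = 0.0069, 6 of 6; 81.4 ± 19.9 against 39.4 ± 12.2 RPKM). Crh (0.31 ± 0.17, adjusted p = 0.12), Pmch (−0.18 ± 0.39, adjusted p = 0.71) and Ttr (−0.39 ± 0.82, adjusted p = 0.7) did not pass, and with the covariate Pmch turned to 1.06 (adjusted p = 0.0025). Of 9 neurohypophysial and releasing hormone genes 6 rose and 0 fell, also adjusted over the list alone (Gnrh1 1.26; relative median 1.02, camera adjusted p = 0.00048, and 0.29 with an estimated correlation). Of 11 feeding and arousal neuropeptides 7 rose and 0 fell (Npy 1.51, Cartpt 1.12; relative median 0.73, adjusted p = 0.004, and 0.39 with an estimated correlation).

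The neuronal activity marker Fos (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273) fell 2-fold with noise in free-moving mice (log2 −1 ± 0.29, limma adjusted p = 0.0036, lower in 5 of 6 title numbers; 9.34 ± 3.35 against 19.1 ± 6.08 RPKM, n = 6 each), and did not pass with the covariate (−0.78, adjusted p = 0.054). Of 16 immediate early genes 11 fell (Nr4a2 −0.90, Nr4a3 −0.86, Jun −0.72) and 1 rose (Npas4 1.04), and 2 fell with the covariate; the list did not pass camera (relative median −0.56, adjusted p = 0.18). Gpr165 fell 8.1-fold (−3.02 ± 0.29, adjusted p = 1.9e-10, 6 of 6; 2.12 ± 2.09 against 17.3 ± 2.09 RPKM) and Gabrb2 6.48-fold (−2.70 ± 0.17, adjusted p = 1.1e-15; 0.785 ± 0.619 against 7.35 ± 1.31 RPKM). Of 14 GABA-A receptor subunits 10 fell and 0 rose (relative median −0.47, adjusted p = 0.011, and 0.8 with an estimated correlation), and of 10 thalamus genes 8 fell and 0 rose (Plekhg1 −1.11, Slitrk6 −1.06; relative median −0.68, adjusted p = 0.035, and 0.83 with an estimated correlation).

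Genes of translation, respiration and interferon response rose with noise in free-moving mice. Ifi27l2a (ENSMUSG00000079017.3, chromosome 12, 103442167 to 103443680), an interferon-induced gene, rose 4.05-fold (log2 2.02 ± 0.25, limma adjusted p = 3.9e-08, higher in 6 of 6 title numbers; 16.1 ± 4.87 against 3.76 ± 1.6 RPKM, n = 6 each). Of 18 interferon-stimulated genes 12 rose (Ifitm3 1.23, Bst2 1.19) and 2 fell, 13 and 2 adjusted over the list alone (relative median 0.64, camera adjusted p = 0.00014, and 0.29 with an estimated correlation). Of 36 cytosolic ribosomal protein genes 35 rose and 0 fell (Rpl32 1.08, Rpl23 1.05; relative median 1.17, adjusted p = 6.3e-24, and 0.29 with an estimated correlation). Of 30 nuclear-encoded respiratory chain genes 20 rose and 5 fell (Cox6c 1.07, Ndufb9 0.99; adjusted p = 1.8e-06, and 0.58 with an estimated correlation). All 13 mitochondrially encoded genes rose (adjusted p = 4.4e-06, and 0.71 with an estimated correlation), 5 after quantile normalization. Ependymal and tanycyte genes rose in 7 of 10 (Rax 1.14, Dynlrb2 0.95; adjusted p = 0.01, and 0.39 with an estimated correlation). Meningeal fibroblast genes rose in 6 of 10 (Igf2 1.04, Ogn 0.97; adjusted p = 0.01, and 0.8 with an estimated correlation) and blood cell genes in 5 of 7 (Hba-a1 1.12, Hbb-bs 1.01; adjusted p = 0.035, and 0.8 with an estimated correlation). On the largest component left by series and title number, loadings rising with the mitochondrial share went with shorter genes (Spearman rho with length −0.3994, 13535 genes). Lists were not tested again with length trends removed. A length-linked difference between libraries thus cannot be told apart from a list effect, here or in the other comparisons.

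Other lists held called genes with noise in free-moving mice without standing apart from all genes by camera, with limma behind each call. Both cold-inducible RNA-binding protein genes rose (Rbm3 0.55, Cirbp 0.47; adjusted p = 0.23), as did 5 of 15 unfolded protein response genes, with 2 falling (Ddit3 1.14; 0.41). NRF2 and oxidative stress genes rose in 2 and fell in 7 of 14 (Sod1 0.90, Gclm −0.54; adjusted p = 0.71), and thyroid hormone-responsive genes rose in 4 and fell in 3 of 8 (Klf9 −1.14; 0.37). Mural genes rose in 4 and fell in 1 of 9 (Acta2 0.81, Myh11 0.71; adjusted p = 0.26), muscle contractile genes rose in 2 of 3 (Acta1 0.75; 0.26), and choroid plexus genes fell in 3 of 6 (Otx2 −0.73, Kl −0.61; 0.41). Suprachiasmatic nucleus markers rose in 3 and fell in 3 of 9 (Grp 0.42, Syt10 −1.73; adjusted p = 0.76), where the relative median was 0.11 while the test pointed down. Clock output bZIP factors fell in 1 of 4 (Hlf −0.79; adjusted p = 0.51). Opioid and tachykinin precursors rose in 1 of 4 (Pnoc 0.30; adjusted p = 0.26), NF-kB and cytokine genes fell in 1 of 4 (Nfkbia −0.39; 0.91), and striatum genes rose in 1 and fell in 1 of 9 (Rgs9 0.66, Pde10a −0.92; 0.81).

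In all, noise with low pressure raised 2897 and lowered 4983 genes in free-moving mice in limma (36.8% higher, median shift −0.15), 4252 and 4663 after quantile normalization (47.7% higher) and 5180 and 1538 with the covariate (77.1% higher). On the table without mitochondrial genes and rescaled the direction turns as well (5507 and 3143), partly by construction. In all 3 fits 2632 rose and 1482 fell. Mitochondrial RPKM made up 28.3 ± 8.55% against 11.5 ± 1.68% (two-sided exact permutation p = 0.0022, adjusted 0.011).

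The same question in unloaded mice compared the unloaded noise series with the late quiet unloaded series (n = 6 each). Agrp rose 4.44-fold (log2 2.15 ± 0.32, limma adjusted p = 2e-04, higher in 6 of 6 title numbers), Avp 3.21-fold (1.68 ± 0.24, adjusted p = 2e-04, 6 of 6; 4522 ± 1483 against 1373 ± 310 RPKM) and Oxt 2.15-fold (1.10 ± 0.18, adjusted p = 6e-04, 6 of 6; 1768 ± 340 against 828 ± 194 RPKM). Fos fell 3.42-fold (−1.77 ± 0.29, adjusted p = 6e-04, 6 of 6; 6.39 ± 2.17 against 23.9 ± 8.43 RPKM). Fosb, its close relative, fell (−1.68 ± 0.25, adjusted p = 2e-04), and Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984), another activity-induced transcription factor, fell too (−1.53 ± 0.30, adjusted p = 0.0023; 8.07 ± 3.85 against 23.1 ± 7.84 RPKM). Pmch fell (−1.01 ± 0.39, adjusted p = 0.031, 5 of 6), and with the covariate its sign turned (0.14). Crh (−0.07, adjusted p = 0.73), Pomc (0.54, adjusted p = 0.16), Hcrt (−0.14, adjusted p = 0.52) and Ttr (−0.72, adjusted p = 0.46) did not pass.

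Of 16 immediate early genes 15 fell and 0 rose with noise in unloaded mice (Btg2 −1.33, Arc −1.10; relative median −0.72, camera adjusted p = 1.1e-05, and 0.32 with an estimated correlation), 16 adjusted over the list alone. Of 9 neurohypophysial and releasing hormone genes 5 rose and 0 fell (relative median 0.66, adjusted p = 1.2e-06, and 0.04 with an estimated correlation). Ribosomal protein genes rose in 31 of 36 (relative median 0.83, adjusted p = 1.4e-36, and 0.071 with an estimated correlation) and interferon-stimulated genes in 9 of 18, with 1 falling (0.67, adjusted p = 1.1e-07, and 0.05 with an estimated correlation). Of 10 thalamus genes 9 fell (−0.59, adjusted p = 0.012, and 0.68 with an estimated correlation). In limma 924 genes rose and 6238 fell (12.9% higher, median shift −0.28), and 2713 and 3175 after quantile normalization (46.1% higher). On the table without mitochondrial genes and rescaled the direction of the bulk turns, partly by construction, with 3792 higher and 1454 lower. Without title number 13 the fit as deposited called 1281 genes. With the covariate 0 passed, against 2286 at an unadjusted p below 0.05, with Avp at 1.40 ± 0.27 (adjusted p = 0.066), Agrp at 1.57 (0.069) and Fos at −1.57 (0.069). In these series mitochondrial genes held 33.6 ± 17.3% of RPKM against 14.0 ± 1.32% (two-sided exact permutation p = 0.048, adjusted 0.068).

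**Figure D2:**
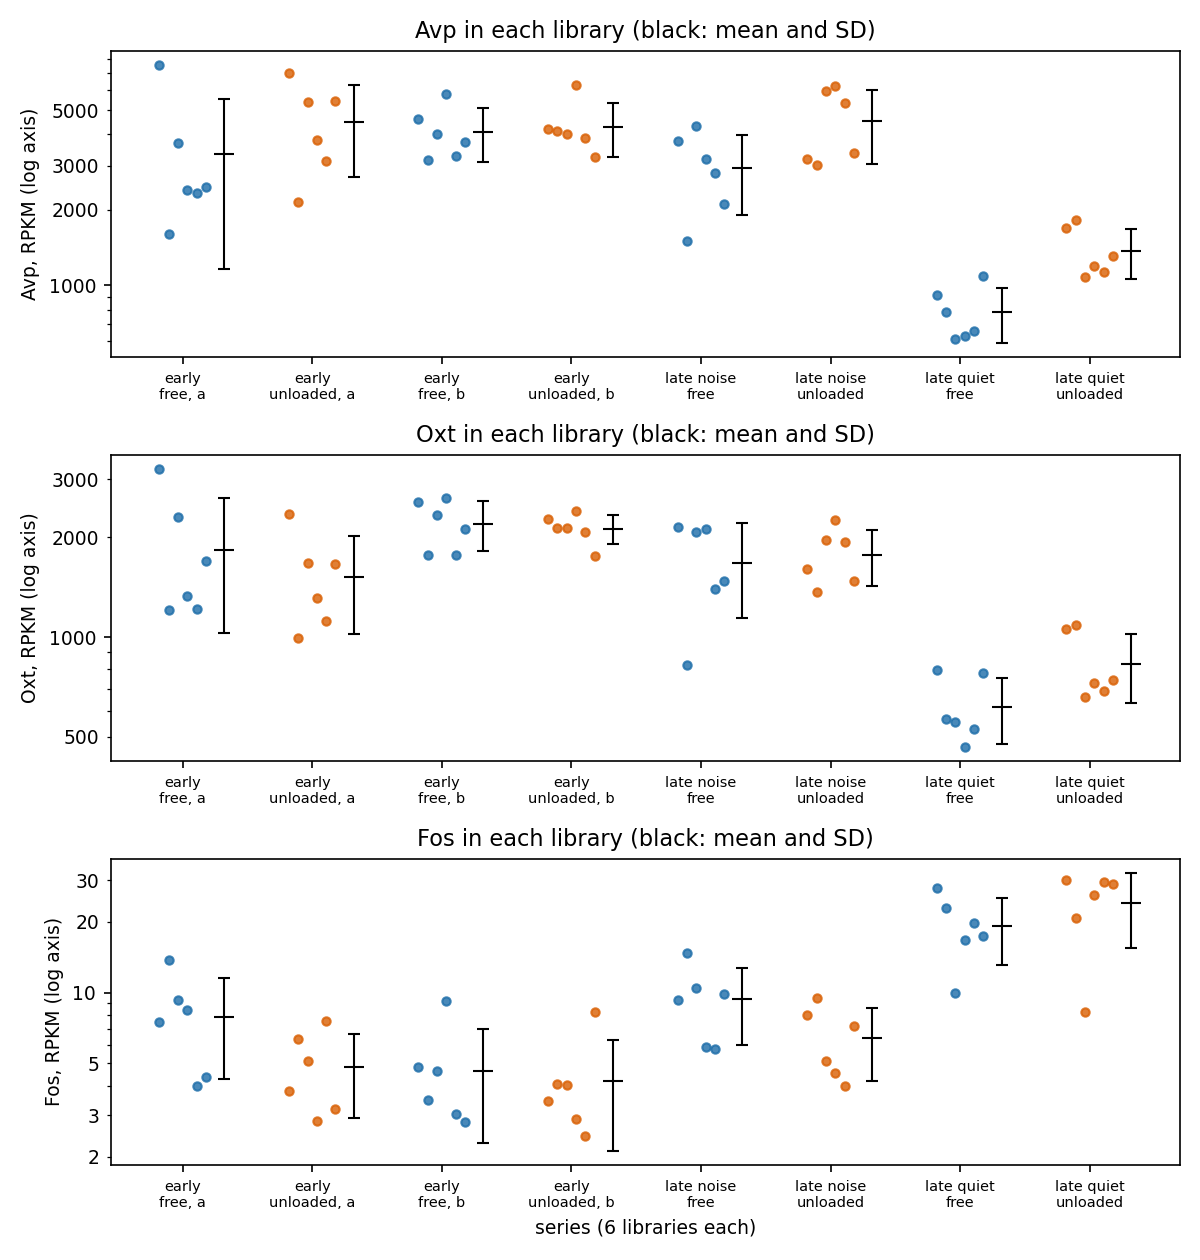
Avp, Oxt and Fos in RPKM on a logarithmic scale (vertical axes) in each library of the 8 series (horizontal axes), with free-moving in blue, unloaded in orange, and black marks for mean and SD. Avp and Oxt are lowest and Fos highest in the late quiet series.

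To measure unloading, noise and low pressure together, the unloaded noise series was compared with the late quiet free-moving series (n = 6 each). Agrp rose 11.04-fold (log2 3.46 ± 0.32, limma adjusted p = 6.3e-11, higher in 6 of 6 title numbers; 50.4 ± 27.1 against 3.74 ± 1.55 RPKM) and Npy 4.88-fold (2.29 ± 0.22, adjusted p = 1.8e-10; 175.7 ± 79.9 against 32.4 ± 3.75 RPKM). Avp rose 5.65-fold (2.50 ± 0.24, adjusted p = 2.6e-10, 6 of 6), Lrg1 5.03-fold (2.33 ± 0.23, adjusted p = 5.1e-10), Oxt 2.89-fold (1.53 ± 0.18, adjusted p = 1.4e-08) and Crh by 0.47 ± 0.17 (adjusted p = 0.016). Fos fell 2.84-fold (−1.51 ± 0.29, adjusted p = 3.2e-05, 6 of 6). Pomc (0.30, adjusted p = 0.44), Hcrt (0.29, adjusted p = 0.17), Pmch (−0.81, adjusted p = 0.068) and Ttr (0.45, adjusted p = 0.64) did not pass. Heat shock chaperones fell in 10 of 13 (Hspa1a −1.77, Dnajb1 −1.34; relative median −0.44, camera adjusted p = 0.068), cholesterol synthesis genes in 12 of 17 (adjusted p = 0.034, and 0.74 with an estimated correlation) and immediate early genes in 13 of 16, with 1 rising (adjusted p = 0.045, and 0.74 with an estimated correlation). Oligodendrocyte precursor genes rose in 1 and fell in 4 of 7 (0.69), and cortex and hippocampus genes rose in 2 and fell in 3 of 8 (0.55). In all 2483 genes rose and 6409 fell (27.9% higher, median shift −0.27), 4377 and 4870 after quantile normalization (47.3% higher) and 4311 and 2026 with the covariate. Without mitochondrial genes and rescaled (5776 and 3378) the direction turns too, there partly by construction. The share of mitochondrial RPKM was 33.6 ± 17.3% against 11.5 ± 1.68% (two-sided exact permutation p = 0.011, adjusted 0.019).

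Whether unloading acted differently with noise than without was tested as an interaction in the late series (n = 6 each). Gabrb2 fell with unloading in quiet (−1.92) and not with noise, and the difference was 2.10 ± 0.24 (limma adjusted p = 3.6e-07, 6 of 6 title numbers). Klhl11 differed by 2.10 ± 0.24 (adjusted p = 3.9e-07, 6 of 6). This interaction and the next use the late quiet free-moving series, in which Gabrb2 and Klhl11 were high. Npas4 rose in quiet (1.32) and its effect was lower with noise by −1.43 ± 0.24 (adjusted p = 0.00033, 6 of 6), and Hcrt differed by −1.02 ± 0.27 (adjusted p = 0.022, 6 of 6). Avp (−0.18 ± 0.35, adjusted p = 0.85), Oxt (−0.30, adjusted p = 0.6) and Fos (−0.77, adjusted p = 0.31) showed no difference that passed. Ribosomal protein genes differed in 1 of 36, lower, and 19 adjusted over the list alone (camera adjusted p = 1.4e-07, and 0.97 with an estimated correlation). In all 66 genes had a higher and 534 a lower unloading effect with noise (11% higher, median shift −0.125; 2607 at an unadjusted p below 0.05), 512 and 511 after quantile normalization (50.05% higher) and 261 and 2286 with the covariate. Without title number 13 the count dropped to 59 genes, 25 higher and 34 lower.

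Whether unloading acted differently late in quiet than early was tested as a second interaction (n = 6 and 6 late, 12 and 12 early). The effect on Klhl11 was lower late by −2.25 ± 0.21 (limma adjusted p = 1.5e-09, 6 of 6 title numbers) and on Gabrb2 by −2.01 ± 0.20 (adjusted p = 6.7e-09, 6 of 6). It was higher late on Npas4 (1.44 ± 0.21, adjusted p = 1.5e-05) and on Oxt (0.56 ± 0.22, adjusted p = 0.048, 6 of 6). Avp (0.52, adjusted p = 0.16) and Fos (0.64, adjusted p = 0.15) did not pass. Ribosomal protein genes had a higher effect late in 31 of 36 (relative median 0.78, camera adjusted p = 6.2e-23, and 0.29 with an estimated correlation), and GABA-A receptor subunits a lower one in 9 of 14 (adjusted p = 0.0089, and 0.82 with an estimated correlation). In all 1092 genes had a higher and 3497 a lower effect late (23.8% higher, median shift −0.22), and 2604 and 2841 after quantile normalization (47.8% higher). The direction turns with the covariate, with 1374 higher and 397 lower (77.6% higher). It also turns on the table without mitochondrial genes and rescaled, partly by construction, with 3923 and 1263. As deposited the count was 1818 without title number 17, 2003 without 9 and 2260 without 13.

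The late quiet free-moving series was compared with both early free-moving series (n = 6 and 12); period and age change together here. Avp fell 4.47-fold (log2 −2.16 ± 0.21, limma adjusted p = 1.9e-11, lower in 6 of 6 title numbers; 782 ± 193 against 3720 ± 1662 RPKM). Oxt (−1.67 ± 0.16, adjusted p = 8.1e-12; 615 ± 137 against 2013 ± 626 RPKM), Agrp (8.18-fold, −3.03 ± 0.28, adjusted p = 4.3e-12) and Pomc (−1.28 ± 0.29, adjusted p = 0.00011) fell too. Fos rose 3.07-fold (1.62 ± 0.25, adjusted p = 3.2e-07, 6 of 6; 19.1 ± 6.08 against 6.28 ± 3.37 RPKM) and Gpr165 11.49-fold (3.52 ± 0.25, adjusted p = 1.1e-14, 6 of 6). Pmch rose by 1.38 ± 0.34 (adjusted p = 0.00038), and with the covariate its sign turned (−0.62, adjusted p = 0.11). Crh (−0.24, adjusted p = 0.14), Hcrt (−0.31, adjusted p = 0.076) and Ttr (0.67, adjusted p = 0.39) did not pass. Ribosomal protein genes fell in 35 of 36 (relative median −1.54, camera adjusted p = 4.1e-29, and 0.19 with an estimated correlation), neurohypophysial and releasing hormone genes in 6 of 9, with 1 rising (−1.39, adjusted p = 6.4e-05, and 0.17 with an estimated correlation), and immediate early genes rose in 14 of 16, with 1 falling (adjusted p = 0.14). In all 8283 genes rose and 2460 fell (77.1% higher, median shift 0.43), 5560 and 5025 after quantile normalization (52.5% higher) and 2175 and 4023 with the covariate (35.1% higher), and without mitochondrial genes and rescaled 4092 and 6599. The mitochondrial share was 11.5 ± 1.68% against 43.2 ± 12.2% (two-sided exact permutation p = 0.00011, adjusted 0.0011).

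In unloaded mice the late quiet series was compared with both early series in the same way (n = 6 and 12). Fos rose 4.79-fold (log2 2.26 ± 0.25, limma adjusted p = 1.8e-07, higher in 6 of 6 title numbers; 23.9 ± 8.43 against 4.50 ± 1.92 RPKM), with Fosb (1.85 ± 0.22, adjusted p = 4.4e-07) and Egr1 (1.85 ± 0.26, adjusted p = 1e-05). Avp fell 3.11-fold (−1.64 ± 0.21, adjusted p = 2.4e-06, 6 of 6; 1373 ± 310 against 4391 ± 1394 RPKM), Agrp 4.69-fold (−2.23 ± 0.28, adjusted p = 1.1e-06), and Oxt (−1.11 ± 0.16, adjusted p = 1.4e-05) and Pomc (−0.89 ± 0.29, adjusted p = 0.011) fell too. Crh (−0.06, adjusted p = 0.76), Hcrt (−0.26, adjusted p = 0.19), Pmch (0.69, adjusted p = 0.09) and Ttr (1.07, adjusted p = 0.21) did not pass. All 16 immediate early genes rose (relative median 1.02, camera adjusted p = 1.8e-09, and 0.18 with an estimated correlation), 14 with the covariate. Neurohypophysial and releasing hormone genes fell in 5 of 9 (−0.80, adjusted p = 4.8e-07, and 0.034 with an estimated correlation). In all 5311 genes rose and 1168 fell (82.0% higher, median shift 0.21), 3349 and 3035 after quantile normalization (52.5% higher) and 844 and 1502 with the covariate (36.0% higher), and without mitochondrial genes and rescaled 2617 and 3334. The mitochondrial share was 14.0 ± 1.32% against 27.4 ± 13.1% (two-sided exact permutation p = 0.011, adjusted 0.019).

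**Figure D3:**
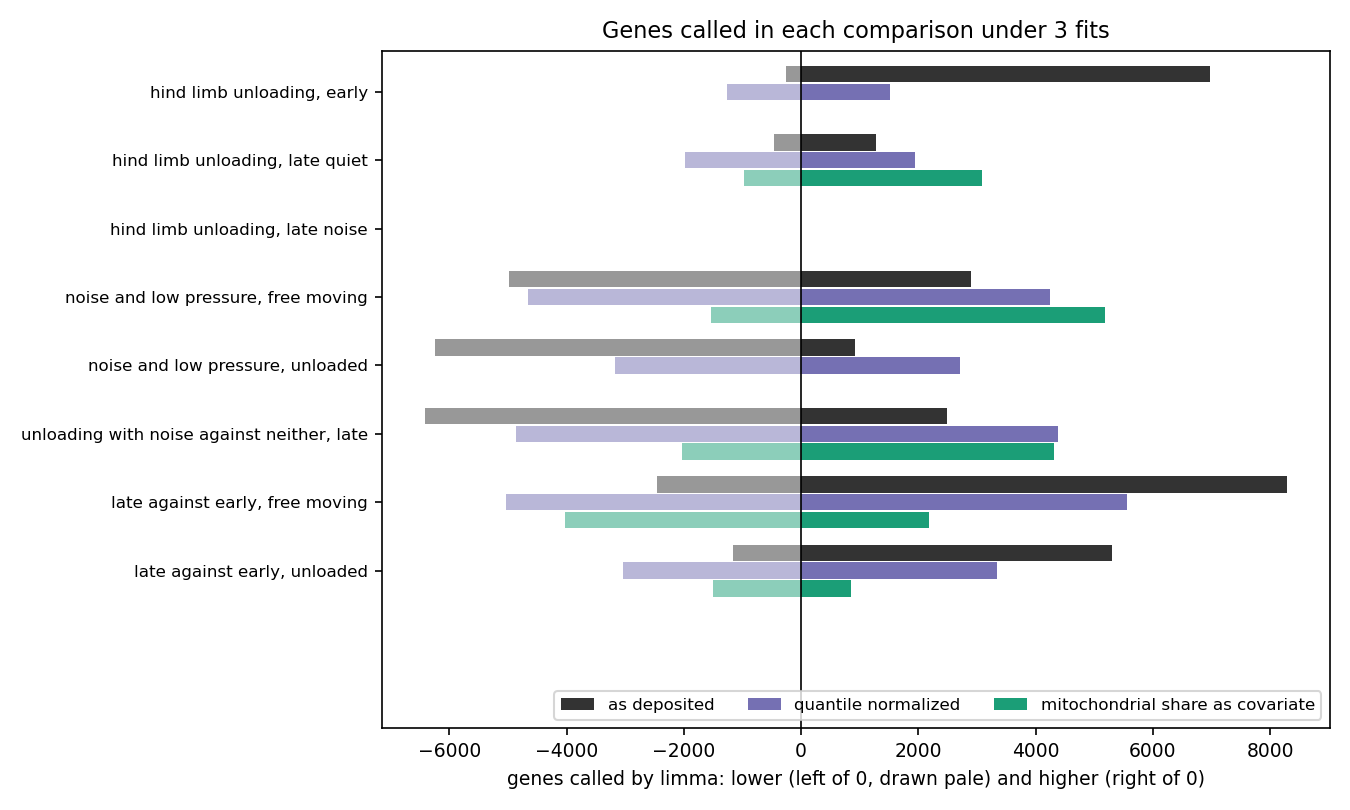
Number of genes called by limma (horizontal axis; higher to the right, lower drawn pale to the left of 0) in 8 comparisons (vertical axis), each as deposited, after quantile normalization and with the mitochondrial share as covariate. The split between higher and lower depends on the scaling.

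Series sharing 1 label show how far series differ without a named difference (n = 6 each). In early free-moving mice series b differed from a in 35 genes by limma (7 higher, 28 lower; 2099 at an unadjusted p below 0.05). After quantile normalization it differed in 639 genes, and with the covariate in 782. The 35 calls are not stable, with 0 without title number 1 or 21 and with only the compared series, and 272 without number 9. The oxidative stress gene Osgin1 was higher by log2 0.73 ± 0.15 (adjusted p = 0.02, 6 of 6 title numbers; 1.29 ± 0.214 against 0.59 ± 0.228 RPKM), and the pseudouridine synthase gene Dkc1 was lower (−0.77 ± 0.14, adjusted p = 0.014; 2.59 ± 0.518 against 4.82 ± 1.21 RPKM). In early unloaded mice 59 were higher and 55 lower (4047 at an unadjusted p below 0.05, median shift −0.16), with the peptide genes Prlh (1.17 ± 0.26, adjusted p = 0.037, 6 of 6; 6.50 ± 1.46 against 2.72 ± 1.23 RPKM) and Ghrh (0.76 ± 0.19, adjusted p = 0.047) among the higher. These 114 calls are not stable either, with 0 without title number 9, 17 or 21 and 5370 without number 1, and 6 of 100 groupings called at least as many. After quantile normalization the unloaded series differed in 1577 genes, and with the covariate in 0. Ribosomal protein genes stood apart there (2 of 36 higher, 24 adjusted over the list alone, camera adjusted p = 1.3e-25, and 0.24 with an estimated correlation). Taken pair by pair, early unloaded series a differed from free-moving a in 5748 genes and from free-moving b in 8244, while unloaded series b differed in 0 and 3. No difference in mitochondrial share passed between series of 1 label (two-sided exact permutation p = 0.72 free-moving and 0.071 unloaded).

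To ask which genes follow the title number, a curve with 24 as period was fitted to all 48 libraries (limma, adjusted p over 13685 genes). Clock genes did. Dbp (ENSMUSG00000059824.12, chromosome 7, 45705088 to 45710203), a clock output factor, had an amplitude of log2 0.60 ± 0.08 and its peak at 20.8 (2.31-fold from trough to peak, adjusted p = 2.9e-05). Per2 (ENSMUSG00000055866.9, chromosome 1, 91415982 to 91459324) had 0.48 ± 0.09 with its peak at 0.1 (adjusted p = 0.0015), and Nr1d1 (ENSMUSG00000020889.11, chromosome 11, 98767932 to 98775333) 0.42 ± 0.08 with its peak at 18.1 (adjusted p = 0.0038). Arntl (ENSMUSG00000055116.8, chromosome 7, 113207465 to 113314126), a core clock activator, had 0.28 ± 0.04 with its peak at 8.5 (adjusted p = 2.2e-05), and Ciart 0.44 ± 0.05 at 20.2 (adjusted p = 1.8e-06). Per3 (0.34), Nr1d2 (0.30), Cry1 (0.21), Nfil3 (0.25) and Tef (0.25) were also called, 10 of the 19 clock genes, 12 adjusted over the list alone and 14 with the covariate. Not called were Per1 (0.26, adjusted p = 0.051), Bhlhe41 (0.20, adjusted p = 0.12), Npas2, Cry2, Clock, Rora, Rorb, Bhlhe40 and Hlf.

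The largest amplitudes outside the clock belonged to Plin4 (log2 0.90 ± 0.10, peak at 1.5, 3.5-fold, limma adjusted p = 6e-07, n = 48) and Fabp7 (0.89 ± 0.07, peak at 14.6, 3.42-fold, adjusted p = 3e-12), a brain fatty acid binding protein. The chaperone genes Hspa1b (0.72, peak at 3.4) and Hspa1a (0.57, peak at 3.7), the corticosteroid targets Sgk1 (0.59, peak at 22.6) and Fkbp5 (ENSMUSG00000024222.17, chromosome 17, 28399094 to 28517527; 0.53, peak at 0.1, adjusted p = 8.1e-06), and Mfsd2a (0.51, peak at 2.1) followed. In all 241 genes were called, 484 with the covariate, 499 after quantile normalization and 174 in all 3 fits. The count ran from 82 without title number 17 to 818 without number 1, and 5 of 100 assignments of title numbers called at least as many genes, so chance is not excluded for it. No gene differed in its rhythm with early unloading, with late unloading or with late noise by limma (0, 0 and 0 genes; 3455, 113 and 1509 at an unadjusted p below 0.05). These counts are not stable, as 4211 genes differed with early unloading when the library of early free-moving series a number 1 was left out, and 3224 with late noise when title number 1 was left out of every series.

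**Figure D4:**
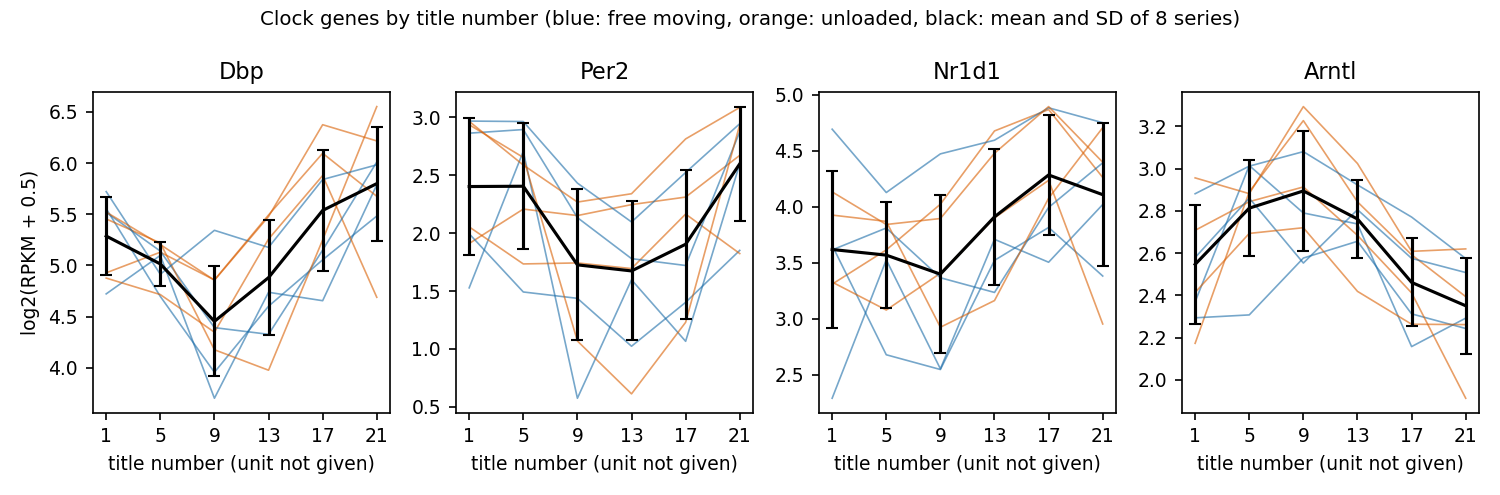
Dbp, Per2, Nr1d1 and Arntl as log2(RPKM + 0.5) (vertical axes) against the title number (horizontal axes, unit not labelled), with free-moving libraries in blue and unloaded libraries in orange. Arntl runs opposite to Dbp.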

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

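The regrouping of libraries and the interactions were planned, and every other test in this part was chosen only after the data had been seen. For the removal of length and GC trends the prediction was written before its value was seen, and for the others it was written only after the result was seen. A library was picked out where its value lay far from the next value of its series by a Dixon test at the level of 0.05, so chance alone picks out about 1 in 20 groups. Of 104 pairs of measure and series over 13 measures, 22 stood apart.

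The mitochondrial share was far above the other libraries of the series in early unloaded series a number 1 (48.16%), early unloaded series b number 21 (50.98%) and the late quiet unloaded series number 21 (16.57%). Early unloaded series a number 1 also had the fewest genes above 0 of its series (16018), and number 21 of that series the highest ribosomal protein share (6.614%). The hemoglobin share was highest of its series in early free-moving series a number 1 (1.048%), late quiet unloaded number 1 (0.6901%) and unloaded noise number 9 (0.6035%). The depth of late quiet free-moving number 21 (48.34 M reads) was the highest of its series.

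Pituitary hormone transcripts stood apart in several libraries. Gh, growth hormone, was highest of its series in early unloaded series b number 9 (6.47 RPKM) and unloaded noise number 1 (3.154 RPKM). Prl, prolactin, was highest in early unloaded series a number 9 (1854 RPKM), early free-moving series a number 1 (2.562), early unloaded series b number 17 (0.7621), late quiet unloaded number 17 (0.6597), early free-moving series b number 9 (0.3375) and unloaded noise number 1 (0.1134). Apart from the 1854 RPKM, these Gh and Prl values are low. Most other libraries of those series lay at or near 0, so the rule picks out small values there. Pomc was lowest of its series in early unloaded series b number 21 (48.26 RPKM) and free-moving noise number 5 (44.52 RPKM). Ttr was lowest in early free-moving series a number 5 (0.7139 RPKM) and highest in late quiet free-moving number 17 (373.4 RPKM), and Fos was lowest in late quiet unloaded number 9 (8.232 RPKM). The effect of unloading differed between noise and quiet in 600 genes, and between late and early in 4589 genes.

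Libraries lie along 1 axis with the mitochondrial share. Dilution of all other genes by mitochondrial reads could be the only cause. With those genes left out and each library set to the same sum, the first component still followed the log2 odds of the mitochondrial share (r = 0.8986). With the rest divided by their share of the total instead, r was 0.935 (rho 0.929, 0.933 without the 2 farthest libraries, permutation p = 1e-04 for both, the smallest the permutations can give). That division scales each library by the mitochondrial share itself, so the 0.935 is partly built in, and the same-sum value is the one that speaks against dilution alone. Length and GC trends of single libraries might also produce it, but with them removed r was 0.921 (rho 0.915, 0.921 without the 2 farthest, permutation p = 1e-04 for both, again the smallest). The permutations exchanged libraries freely across series, so these p-values do not part the axis from differences between series. Within series, where unloading does not vary, lay 31.5% of the variance of the axis, so unloading may contribute and is not the only cause. Early unloading calls ended with the covariate. The share itself differed with early unloading (27.4 ± 13.1% against 43.2 ± 12.2%), so the end of these calls does not count against unloading. Other biological or handling differences between pools stay open as untested.

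Peptide hormone, immediate early and thalamus genes differ between the late quiet series and the others. If the mitochondrial-share axis alone were the cause, few calls of the noise comparison in free-moving mice should survive the covariate, and 53.8% did, 100% for the hormone genes, 25% for the immediate early genes and 62.5% for the thalamus genes. Of all 7880 genes called there as deposited, 2897 rose and 4983 fell. In all 3 fits, which asks more than the covariate alone, 2632 rose and 1482 fell. Rises thus kept their calls far more often than falls, and the covariate moved the median of all genes from −0.152 to 0.169. The called hormone genes rose and most called immediate early genes fell, so their shares are not particular to these lists. The linear covariate did not take up the calls of the hormone genes in free-moving mice (median log2 1.07 to 0.82). It cannot exclude the axis, as the shares do not overlap (8.947% to 13.51% quiet, 15.12% to 38.8% noise). In unloaded mice noise left 0 calls with the covariate. Avp, Agrp and Fos kept most of their change there and Pmch changed sign, so the lost calls decide nothing. In free-moving mice the axis could explain the lost calls of the immediate early genes. The covariate did not take up all of their change (median log2 0.86 to 0.5). For the thalamus genes, with 5 of 8 calls kept, the axis cannot be told apart from a separate effect. More thalamic tissue in the late quiet pools cannot be told apart either, since the hypothalamic transcription factors lay 0 from all genes while 5 of 10 thalamus genes were higher. Avp in the late free-moving noise series lay −0.11 from the early free-moving series with the covariate, but noise changed there together with age or period and opposite effects would give the same value, so age, noise, pressure and handling stay open.

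In early unloaded series a number 9 pituitary tissue in the pool is a possible source, as 6 of 8 anterior pituitary genes were at least 10-fold above the median of the other 5 libraries, with 0.5 RPKM added to both values. Gh was 10150 against 0.0601 RPKM and Cga 100.7 against 3.71 RPKM; Prl was 1854 against 0, where a fold without that addition cannot be given. Early unloading is unlikely as the cause, since 0 of the 11 other early unloaded libraries had Gh above 100 RPKM, a limit set after the result was seen. The highest of them had 53.6 RPKM, and an effect in 1 pool alone cannot be excluded this way.

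Regrouping exchanges single libraries between series, so it tests chance assignment of libraries and not differences between whole series. Each late condition is 1 series, so a difference between series unrelated to the condition would pass as well. Only the real grouping (1 of 100) reached its count for late quiet unloading, noise in free-moving mice and unloading with noise against neither. The same held for both late against early comparisons and the interaction with period. In this order the highest others were 395, 6820, 8560, 10013, 6131 and 1 genes. Chance assignment of single libraries is thus unlikely for these, without adjustment over the results. Evidence against it is weaker for early unloading (2 of 100, highest other 9229), noise in unloaded mice (2, 7987), the interaction with noise (2, 3187) and the free-moving series of 1 label (3, 902). The last of these has no named difference between its series, so a low number of splits does not point to the condition. Chance cannot be excluded for late unloading with noise (5 of 100, highest other 5035), the unloaded series of 1 label (6, 7296), and the common rhythm (5, 6594). For the rhythm differences with early unloading, late unloading and late noise the real count is 0, so all 100 splits reach it and the test says nothing; the highest others were 9425, 102 and 7306. Some splits called several times the real count, and what those splits follow was not tested.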

How the results depend on the processing

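The alternatives for the mitochondrial covariate, length and GC, the table without mitochondrial genes and the 2 fits without 1 library were chosen only after the result was seen; the others were planned. Of 4144 planned values for 341 gene results 3649 stayed on the same side, 439 were weaker, 42 stronger and 14 reversed. Where a value below differs, the cause was not tested. With pseudocount 0.1 the unloaded series of 1 label gave 33 genes. Without a filter late noise unloading gave 1, the unloaded series of 1 label 9 and the rhythm difference with noise 1. With quantile normalization early unloading gave 2784 genes, late quiet unloading 3920, late noise unloading 4, the noise interaction 1023, the free-moving and unloaded series of 1 label 639 and 1577, rhythm 499 and its difference with early unloading 2. Array weights, whose convergence tolerance was not achievable, gave late quiet unloading 7329, late noise unloading 1764, noise in unloaded mice 4359, the interactions 6288 and 9545, the series of 1 label 3658 and 7843, rhythm 1240 and its differences 5812, 1778 and 8666. Without the term for the title number late noise unloading gave 1 and the series of 1 label 14 and 1. With only the compared series early unloading gave 4618, late quiet unloading 7106, late noise unloading 7, the noise interaction 1487, the series of 1 label 0 and 306, and the rhythm difference with noise 1. Early unloaded series b alone gave 0 and 3 genes against free-moving a and b.

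With the covariate early unloading gave 1 gene, late quiet unloading 4055, noise in unloaded mice 0, late against early 6198 and 2346, the interactions 2547 and 1771, the series of 1 label 782 and 0, and rhythm 484. With length and GC removed early unloading gave 2848, noise in unloaded mice 4681, the series of 1 label 173 and 1302, rhythm 596 and its difference with early unloading 1. Without mitochondrial genes early unloading gave 3484, late quiet unloading 2652, the noise interaction 312, the series of 1 label 399 and 1369, rhythm 452 and its early difference 19. Without early unloaded series a number 9 the series of 1 label gave 154 and 5, and without early free-moving series a number 1 they gave 4 and 482, and the early rhythm difference 4211. Of the 116 list calls at the preset correlation 5 stayed with an estimated one. With the covariate 79 list calls passed at the preset correlation and 0 with an estimated one.

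Leaving out 1 title number at a time gave early unloading 0 (without 17) to 8857 (without 1), late quiet unloading 619 (13) to 1716 (1), late noise unloading 1 (5) to 2, noise in free-moving mice 6657 to 7984, and noise in unloaded mice 1281 (13) to 7725. Unloading with noise gave 7356 to 9104, late against early 10174 to 10546 and 4595 to 6061, the noise interaction 59 (13) to 721, and the period interaction 1818 (17) to 5426. The series of 1 label gave 0 (1) to 272 (9) and 0 (9) to 5370 (1), rhythm 82 (17) to 818 (1), and its differences 0 to 1, 0 to 0 and 0 to 3224 (1). The correlations with series of 1 label ran from 0.29 to 0.67 and from 0.68 to 0.84.

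Signs reversed with quantile normalization for mt-Cytb in early unloading (0.11), late against early free-moving (0.12) and the period interaction (−0.11), mt-Co1 late against early free-moving (0.1), and mt-Co3 (0) and Crh (0.23) with noise in unloaded mice. Array weights reversed Oxt (−0.35) and Pmch (0.3) in late noise unloading and Pomc in unloading with noise (−0.14). Without number 17 the value reversed for Ttr, noise and low pressure, free moving (0.98, and −0.91 without replicate 9), and for late against early, free moving (−0.46, and 1.01 without number 1). The covariate reversed mt-Cytb (0.06), mt-Nd2 (0.14) and Oxt (0.01) in early unloading, Pmch with noise in free-moving mice (1.06), Crh (0.15), Hcrt (0.31) and Pmch (0.14) with noise in unloaded mice, mt-Atp8 (−0.07), Pmch (0.61) and Ttr (−0.05) in unloading with noise, and mt-Atp8 (0.22, 0.08) and Pmch (−0.62, −0.17) late against early. Length and GC removal reversed Oxt in late quiet unloading (−0.01), Crh with noise in free-moving mice (0), Pomc (−0.16) and Hcrt (−0.43) in unloading with noise, and Crh (0, 0.05) and Hcrt (0.45, 0.1) late against early. Without mitochondrial genes Avp reversed in early unloading (−0.07), Pmch with noise in free-moving mice (0.13), and Crh (0.32) and Hcrt (0.27) in unloaded mice. In single early pairs Fos was 0.07 (unloaded a against free-moving b), and Oxt 0.31 and Pomc 0.09 (unloaded b against free-moving a). At 28.3 M to 55.3 M reads, depth limits genes with few reads, as 1 read in 2 kb is 0.0177 RPKM in early free-moving series a number 1.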

Other observations

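The comparison of late noise with early series and the fits with the covariate were chosen only after the result was seen, and the correlations between series of 1 label were planned. The late noise series were compared with the early series. With the covariate the free-moving noise series differed from both early free-moving series in 5 genes, all higher, by limma (2074 at an unadjusted p below 0.05; n = 6 and 12), against 6308 higher and 61 lower as deposited and 313 and 187 after quantile normalization. Avp differed there by log2 −0.30 (adjusted p = 0.22) as deposited and Fos by 0.62 (adjusted p = 0.044), and with the covariate by −0.11 (0.86) and 0.48 (0.4). In unloaded mice 2 genes were higher and 0 lower as deposited (508 at an unadjusted p below 0.05), and 4 and 2 with the covariate; Avp differed by 0.04 as deposited (adjusted p = 0.98). Age or period and noise change together in these comparisons, so they do not show which of them acts on Avp.

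Differences between series that share 1 label were set against the noise effect. Across genes, which are not independent replicates, the difference between free-moving series b and a correlated with the noise effect in free-moving mice (r = 0.5071, and 0.3907 with the covariate), and that between unloaded series b and a with the noise effect in unloaded mice (r = 0.785, and 0.362 with the covariate). Regrouped libraries gave values as far from 0 in 23 and 15 of 100 cases, with largest values of 0.6688 and 0.8594, so chance is not excluded. With 1 title number left out they ran from 0.29 to 0.67 and from 0.68 to 0.84.

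Among the 19 clock genes, differences in rhythm that passed over all genes in 0 cases did pass for some genes when adjusted over the list alone, by limma (moderated F test, n = 24 libraries in each comparison). With early unloading these included Per1 (adjusted p = 0.008), Tef (0.008) and Dbp (0.015), and with late noise Rora (0.0023), Per1 (0.0097) and Hlf (0.0097); over all genes the adjusted p-values for Per1 were 0.13 and 0.4. With late unloading none passed (adjusted p = 0.7 for each over the list alone). All of these values are from the fit as deposited. With the covariate 0 genes differed over all genes in each of the comparisons of rhythm. Correlation of the first component with the mitochondrial share ran from 0.6097 to 0.9813 within 6 of the 8 series (n = 6 each). In the late quiet ones r was −0.2249 (free-moving) and −0.04409 (unloaded), where the share hardly varies, so these values do not show whether the relation holds there.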
